A study of Mus musculus with 13 samples.

How the data were processed

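The series holds 13 sequencing libraries from livers of male mice: 12 chromatin immunoprecipitation (ChIP-seq) libraries and 1 input library. Per the labels, the animals carried either a control construct (labelled GFP) or Cre (labelled CRE), and the titles name these groups control and dKO, a knockout that includes the nuclear receptor corepressor NCOR1. Vehicle or dexamethasone, a synthetic glucocorticoid, was injected at 1 mg/kg at zeitgeber time 8, and livers were taken 2 h later at zeitgeber time 10. Per the labels' protocols, chromatin was fixed with 1% formaldehyde for 20 min, and the glucocorticoid receptor (GR) was precipitated with a mix of 3 antibodies at 2 µg each. NCOR1 was precipitated with an antibody raised against amino acids 1944 to 2453 of the protein. The GR libraries were made without size selection, whereas the NCOR1 and input libraries were size selected, per the labels.

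The deposited files are 7 peak lists, 4 for GR and 3 for NCOR1, each for a whole group. Labels of every library of a group point to the same list, so replicates were pooled before peaks were called and no list gives a value per replicate. Each GR list stands for 2 libraries, the NCOR1 control dexamethasone list for 2, and the NCOR1 control vehicle and dKO vehicle lists for 1 each. Trim Galore 0.6.4, BWA 0.7.17, HOMER 4.11 and bedtools 2.29.2 with the mm10 build are named in the submitters' processing notes. Peaks were called with HOMER findPeaks at a fixed width of 200 bp against the input, per the file headers. The headers give a minimum of 4-fold over input, 4-fold over the surrounding 10 kb, a p-value of at most 0.0001 for each, and a minimum distance between peaks of 400 bp. A tag threshold of 15 was set for the 4 GR lists, per the file headers, and no such threshold is written in the headers of the NCOR1 lists. The headers name the GR tag directories with a suffix for high sonication, and the NCOR1 ones without it.

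Each peak carries a normalized tag count, a signal in tags per 10 M tags (M for 10 to the power of 6), as deposited by the authors. The findPeaks score of each peak is likewise the authors' value; per the file headers, tags per position were limited, and the score is not defined further. The fold over input is a ratio the authors computed after scaling the deeper library to the shallower one, per the file headers. The p-value of each peak against input is a Poisson value by the authors, per the file headers, and is not adjusted. Fold over the local 10 kb, input tags and clonal fold are other deposited values per peak, per the file headers; the fold over local was used to describe peaks. These per-peak values were used to describe, rank or filter peaks within a list, and no change of a tag count between lists was tested.

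Depth per list is the tag total in the file headers, which ranged from 17.5 to 36.9 M. It sets how many weak peaks can pass the threshold, so a peak missing from a list was not called there at that depth, which does not show that the protein was absent. Shares of peaks are given with 95% Clopper-Pearson intervals, which cover counting error only. With replicates pooled there is no spread between animals, and peaks are not biological replicates, so every interval and p describes these lists.

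A pair of lists was compared by overlap of at least 1 bp. Peaks of the classified list that overlapped a peak of the other list were called shared, and the rest were called condition-only (for example dexamethasone-only). Chance overlap was measured with 100 seeded circular shifts of each list. Overlap calls were checked against bedtools 2.31.1 on 14 pairs of lists, and 0 of 899940 calls differed. Because stronger peaks overlap more often, co-occupancy was tested by Fisher's exact test over peaks and by a Cochran-Mantel-Haenszel odds ratio over 5 classes of normalized tag count (5 equal parts of the classified list), the latter being the value given unless stated. For NCOR1 at GR peaks, NCOR1 control peaks that overlapped the dKO list were removed beforehand. The stratified test was tested on simulated data built from the real lists: for planted odds ratios of 1, 1.5 and 0.67 it returned means of 1.01, 1.49 and 0.67 over 20 runs each, where the crude odds ratio returned 0.603, 0.861 and 0.417. In these simulations strength acted only through the same 5 classes. They therefore check the calculation and cannot show whether differences of strength within a class bias the real values.

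No genome sequence was used here; the gene table used gives gene bodies on GRCm38.p6, the assembly that mm10 names, without strand. A peak was therefore assigned to the protein-coding gene whose body was nearest within 100 kb (21887 genes), in place of the nearest transcription start planned at first. Peaks near promoters could not be counted as such, and the share within 1000 bp of either gene end is given in their place. Exons, introns and binding motifs in the peaks were not analysed here. For each of 13 gene lists the share of condition-only peaks among peaks assigned to its genes was compared with that of all other assigned peaks. The test was a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 156 tests (13 lists in 12 classes). The lists were glucocorticoid receptor targets, gluconeogenesis, lipogenesis, fatty acid oxidation and ketogenesis, circadian clock, bile acid and cholesterol metabolism, thyroid hormone and LXR targets, inflammation and acute phase, hepatocyte identity, Kupffer cell and other leukocyte markers, endothelial, stellate and cholangiocyte markers, neuronal genes, and corepressor complex and nuclear receptors. On simulated lists over the dexamethasone comparison of genotypes, 5.2% of 500 random lists had Fisher p under 0.05, and 53 of 61 lists planted with a lost share of 65% were found at p under 0.001.

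The comparisons, lists, tests, alternatives and the rule for named genes were fixed before the data were examined, apart from the additions given below. Not part of that plan were GR at classes of NCOR1 peaks and NCOR1 of each treatment in lists of 37700 peaks. Nor were dKO-only NCOR1-antibody peaks at dKO-only GR peaks, or the tests of how many genes of a gene list had a peak. Genes named are those at the 8 peaks with the highest tag count in each condition-only class, and from each gene list up to 4 members whose condition-only peak had the highest tag count (up to 6 where the list's share differed after adjustment). For 10 further genes (Pck1, G6pc, Tat, Ppargc1a, Fkbp5, Per1, Tsc22d3, Nr1d1, Arntl and Cyp7a1) peaks are given in whatever class. The text names a selection of these, and some items are not reported here. The strongest peaks of each list and the genes with the most condition-only peaks were added after their values were seen. Alternatives tried were other overlap rules, stricter peaks, lists of equal length, autosomes only, all NCOR1 peaks, the NCOR1 list of the other treatment, other ways of assigning genes and a test over genes. Distances of 500 bp, 20 classes of tag count, classes of equal tag count, fold over local and fold over input (5 of each, jointly), gene lists stratified by tag count, the nearest gene end, permutation of genes and removal of peaks with stacked tags were added after the data were seen. Coordinates are 1-based on mm10. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.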

Results

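GR and NCOR1 binding was mapped by ChIP-seq in livers of control and knockout (dKO) mice, 2 h after vehicle or dexamethasone. GR is a ligand-activated transcription factor that turns on gluconeogenic and anti-inflammatory genes in hepatocytes, and NCOR1 is a corepressor scaffold that brings the histone deacetylase HDAC3 to nuclear receptors. GR was profiled in 4 groups of 2 libraries each: control vehicle, control dexamethasone, dKO vehicle and dKO dexamethasone. NCOR1 was profiled in control vehicle (1 library), control dexamethasone (2 libraries) and dKO vehicle (1 library). The design asks where the drug moves GR, whether that binding differs in dKO liver, and how NCOR1 itself responds. Replicates were pooled in each list, so no value has a spread between animals.

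The pooled GR lists rested on 27.5 M tags in control vehicle, 30.0 M in control dexamethasone, 31.1 M in dKO vehicle and 31.9 M in dKO dexamethasone. The NCOR1 lists rested on 17.8 M tags in control vehicle, 36.9 M in control dexamethasone and 17.5 M in dKO vehicle. GR peaks held 5.0% of tags in control vehicle and 7.23% in control dexamethasone, against 3.4% and 4.1% in the matching dKO lists. NCOR1 peaks held 8.52%, 6.38% and 2.07% of tags in control vehicle, control dexamethasone and dKO vehicle. Between 55.0% and 56.8% of peaks in any list lay inside a protein-coding gene. Within 1000 bp of a gene end lay 11.9% of dKO dexamethasone, 12.4% of control dexamethasone, 15.4% of control vehicle and 15.6% of dKO vehicle GR peaks. The same share was 17.1% and 18.9% of NCOR1 peaks in control dexamethasone and control vehicle, and 26.6% in dKO vehicle. Within 5000 bp of a gene end these shares were 25.7%, 26.4%, 29.4% and 29% for GR, and 31.9%, 34.4% and 39.6% for NCOR1.

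The strongest GR peak was the same site in all 4 GR lists. It lay in Klf13, a Krüppel-like factor gene (chromosome 7, 63896967 to 63897167 in control dexamethasone), with normalized tag counts of 724.8 in control vehicle, 777.6 in control dexamethasone, 433.8 in dKO vehicle and 536.4 in dKO dexamethasone. Peaks near Ptpn1 (626.2), Fkbp5 (595.6), Zbtb16 (547.6), Armc12 (512.3) and Zfp36 (424.8), an mRNA-destabilizing protein of the inflammatory response, came among the next strongest of the control dexamethasone list. The Ptpn1 site lay 86.0 kb and the Armc12 site 12.7 kb outside the gene body. Of the control dexamethasone peaks, 16144 (39.5%) were found in all 4 GR lists. NCOR1 had its strongest control vehicle peaks near Ptgds (313.1) and Map3k13 (304.4), and its strongest control dexamethasone peaks near Irs2 (316.1) and the clock gene Npas2 (289.9).

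**Figure D1:**
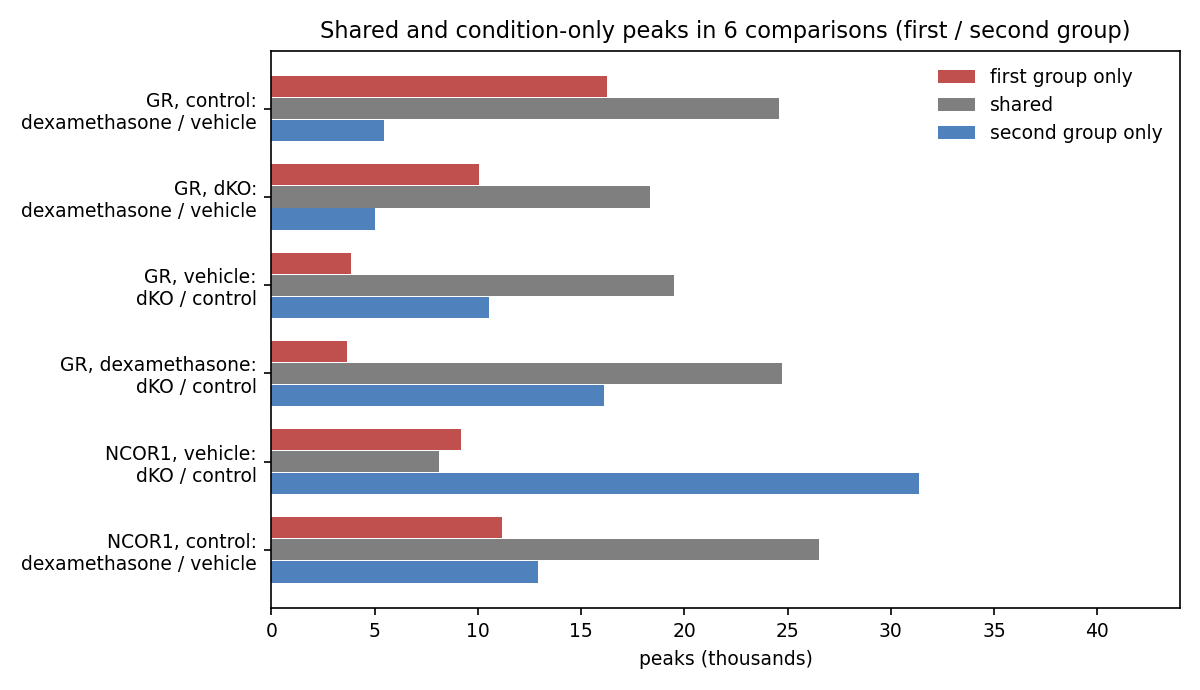
Number of peaks (axis in units of 1000) shared by a pair of lists or called in 1 list alone, for the 6 comparisons. In control liver 16277 GR peaks were dexamethasone-only and 5435 vehicle-only, and for NCOR1 31361 peaks were control-only and 9185 dKO-only.

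In control liver GR peaks were called under dexamethasone and not under vehicle near Zbtb16, Fkbp5, Nfkbia and Tef, among many other genes. The strongest lay near Cdk17 (tag count 223.6; chromosome 10, 93198443 to 93198643), Armc12 beside Fkbp5 (211.8), Zbtb16 (207.5; chromosome 9, 48736418 to 48736618), Rnf169 (191.8), Cdkal1 (191.3), Washc2 (125.5), Nek7 (124.0) and the clock output gene Tef (117.6). Of 40853 dexamethasone peaks, 16277 (39.8%, 95% interval 39.4 to 40.3) had no vehicle peak, whereas 5435 of 30011 vehicle peaks (18.1%, 17.7 to 18.6) had no dexamethasone peak. The vehicle-only peaks were weaker, led by sites near Chd9 (64.6), Bnip3 (61.9), Mmp19 (46.4), Kcnk16 (43.0), Rbms1 (40.8), Lama3 (38.6) and the metallothionein gene Mt2 (38.4). The Chd9, Bnip3, Mmp19, Rbms1 and Lama3 sites each had a dexamethasone peak within 407 bp, so these classes also hold shifted peaks. With lists of equal length both classes are equal by construction, and each held 8864 peaks (29.5%). Most dexamethasone-only peaks were weak: 18.0% of the strongest 20% of the list and 72.2% of the weakest 20% were dexamethasone-only, and above the median tag count 4917 (24.1%) were. For vehicle-only peaks these shares were 3.58%, 39.9% and 6.84% (1026 peaks). Of the strongest 20%, 31.1% of dexamethasone-only and 58.6% of vehicle-only peaks had less than 8-fold over the local 10 kb, near the 4-fold limit of calling, against 13.8% and 9.36% of shared peaks.

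By gene group, 16 glucocorticoid receptor targets had a dexamethasone-only peak, among them Zbtb16 (9 of its 23 peaks), Fkbp5 (6 of 13; strongest 115.4), the NF-κB inhibitor Nfkbia (78.3) and Arrdc2 (54.3). Of the gluconeogenesis list 19 genes did, with Foxo3 (70.8), Klf15 (56.9), Pdk4 (47.6) and Ppargc1a (11 of 25 peaks; 34.1) strongest. Lipogenic genes with such peaks were led by Lpin1 (71.6), Insig2 (52.3), Thrsp (50.0) and Fads1 (36.5), and fatty acid oxidation genes with such peaks included Cyp4a10 (43.1), Ppara (31.3) and Hadhb (23.6). Acute phase genes were led, after Nfkbia, by Orm1 (53.6), Il6ra (52.8) and Saa1 (45.5). At clock genes they were Tef, Per2 (26.8), Clock (25.3) and Rora (21.5; 11 of 36 peaks).

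Hepatocyte identity genes had fewer dexamethasone-only peaks than other genes: 25 of 101 (24.8%) against 40.3%, an odds ratio of 0.487 (Fisher's exact test, adjusted p = 0.0392). Members with such a peak included the transthyretin gene Ttr (36.6), Hnf4a (31.8), the fibrinogen gene Fgb (29.8), Apoa2 (23.5), Serpina1a (20.1) and Cebpa (19.1). Within classes of tag count the odds ratio was 0.870 (Cochran-Mantel-Haenszel test, adjusted p = 0.739), and over genes it was 1.55 (Fisher's exact test, adjusted p = 0.775), so the call was lost by either. The other 12 lists did not pass. Their dexamethasone-only shares were 29.3% for glucocorticoid receptor targets (odds ratio 0.613, Fisher's exact test, adjusted p = 0.0783), 39.2% for gluconeogenesis, 36.4% for lipogenesis, 40.3% for fatty acid oxidation, 28% for clock genes, 26.0% for bile acid and cholesterol genes and 38.7% for thyroid hormone and LXR targets. They were 35.8% for inflammation, 20.0% of 10 peaks for Kupffer cell and other leukocyte markers, 46.0% for endothelial, stellate and cholangiocyte markers, 37.2% for neuronal genes and 41.7% for the corepressor complex and nuclear receptors. No list passed among vehicle-only peaks, where the members with the strongest peaks were Mt2, Dusp1 (32.0), Cyp27a1 (31.3), Fkbp5 (26.9) and Ppara (26.9).

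At Fkbp5, which encodes a cochaperone of GR, the main intragenic peak (chromosome 17, 28420241 to 28420441) was called in all 4 GR lists, with tag counts of 335.3 in control vehicle, 595.6 in control dexamethasone, 66.0 in dKO vehicle and 350.9 in dKO dexamethasone. A further intragenic peak starting at 28424498 was called in both dexamethasone lists (115.4 in control, 83.5 in dKO) and in neither vehicle list. The gene of tyrosine aminotransferase, Tat, had its strongest peak inside the gene (chromosome 8, 109987864 to 109988064), at 140.0, 291.9, 45.0 and 182.7 in the same order of lists. For Per1, a clock gene with a glucocorticoid response element, the values were 344.4, 314.9, 275.0 and 233.8 (chromosome 11, 69096971 to 69097171). The gluconeogenic genes Pck1 and G6pc were bound 0.312 and 6.82 kb outside the gene body. Pck1 (chromosome 2, 173152661 to 173152861) had tag counts of 44.6, 49.1, 23.9 and 43.7, and G6pc (chromosome 11, 101360795 to 101360995) 44.2, 72.6, no peak and 63.1. Ppargc1a, a coactivator of gluconeogenesis, held 16 GR peaks in control vehicle, 25 in control dexamethasone, 10 in dKO vehicle and 13 in dKO dexamethasone. Its strongest site (chromosome 5, 51537167 to 51537367) had 26.9, 73.3, 9.63 and 38.7. Tsc22d3, which encodes GILZ, held 12, 12, 10 and 8 peaks, and a site 26.0 kb outside it (chromosome X, 140513441 to 140513641) had 39.1, 64.1, 19.1 and 58.3. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, held 6, 6, 3 and 5 peaks, and its strongest site (chromosome 4, 6275721 to 6275921) had 35.3, 44.5, 22.8 and 31.7. The clock repressor Nr1d1 (REV-ERBα) held 2, 1, 2 and 1, and Arntl (BMAL1) 4, 2, 1 and 3. For Fkbp5 the counts were 10, 13, 8 and 11, for Tat 4, 5, 4 and 5, for G6pc 5, 6, 5 and 4, for Pck1 2, 3, 2 and 3, and for Per1 2 in each list. Tag counts come from separate lists and no change between them was tested.

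**Figure D2:**
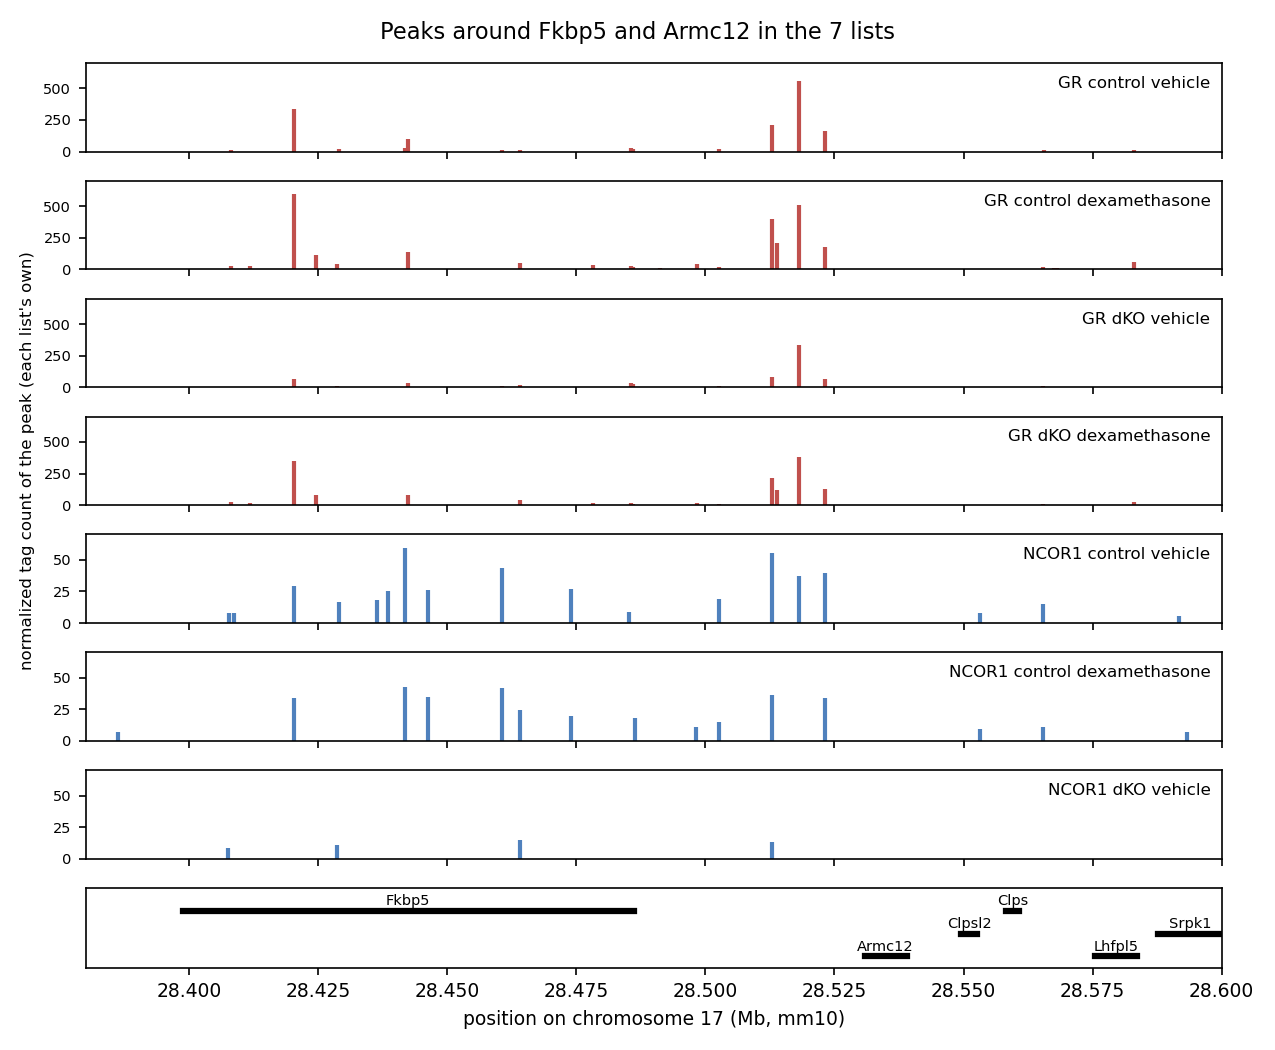
Peaks around Fkbp5 and Armc12 on chromosome 17 (position in Mb, mm10) in the 7 lists; bar height is each list's own normalized tag count, and black bars are gene bodies. The main Fkbp5 peak stood at 335.3, 595.6, 66.0 and 350.9 in the control vehicle, control dexamethasone, dKO vehicle and dKO dexamethasone GR lists.

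In dKO liver, too, dexamethasone-only GR peaks were called near Fkbp5, Zbtb16, Tat and G6pc. Fkbp5 had 5 dexamethasone-only and 2 vehicle-only peaks, Tat 1 and 0, and G6pc 2 and 3. Of the peaks, 10048 of 28378 dexamethasone peaks (35.4%, 34.9 to 36.0) had no vehicle peak, and 5032 of 23362 vehicle peaks (21.5%, 21.0 to 22.1) had no dexamethasone peak. The strongest dexamethasone-only peaks lay near 1110059E24Rik (143.7), Zbtb16 (131.6), Armc12 (118.5), Anapc16 (112.2), Cldn14 (102.2), St3gal1 (99.2), Rnf144b (95.4) and Cdo1 (89.3), a cysteine dioxygenase. Among gene list members Fkbp5 (83.5), Tef (74.9), G6pc (63.1), Nfkbia (59.9), Tat (40.7), Cyp27a1 (40.4), Nfil3 (37.6; 6 of 7 peaks), Ass1 (33.2) and Insig2 (28.0) led. Vehicle-only peaks were led by Acacb (47.5), Cebpb (44.3), Prxl2b (36.9), Ptpn1 (35.6) and Bnip3 (34.7), the last with a dexamethasone peak 373 bp away. Above the median tag count 3329 peaks (23.5%) were dexamethasone-only and 804 (6.88%) vehicle-only. Fatty acid oxidation genes had dexamethasone-only peaks at 24 of 51 sites, including sites of Ppara (26.0; 5 of 9 peaks) and Cpt1a (19.4). This share was not called by Fisher's exact test (odds ratio 1.57, adjusted p = 0.442), and was called within classes of tag count (2.38, 1.34 to 4.2, Cochran-Mantel-Haenszel test, adjusted p = 0.0467), a test added after the data were seen; permutation of genes did not call it (adjusted p = 0.80).

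GR sites that control liver had under dexamethasone alone were found in dKO liver less often than sites it had in both states. Of the 16277 dexamethasone-only control peaks, 5478 (33.7%) were in the dKO dexamethasone list, against 78.3% of the 24576 shared peaks. At equal strength the odds ratio was 0.212 (0.202 to 0.223). Shared sites were by definition called in a second list, which alone favours their call in a further list, and the odds ratio to expect with no change of genotype was not determined. Among the strongest 20% of peaks 71.4% against 92.7% were found, and among the weakest 20% 17.4% against 45.7%. The 8 strongest dexamethasone-only peaks were all found, with tag counts in dKO from 32.0 near Cdkal1 to 131.6 near Zbtb16.

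Under vehicle, GR peaks were called in control and not in dKO liver near Ptpn1, Zbtb16, Tat and G6pc, among many other genes. Tat and G6pc each had 1 control-only and 1 dKO-only peak, with 4 and 5 peaks in either list. The strongest control-only peaks lay near Myom3 (94.3), the phosphatase gene Ptpn1 (86.1 and 60.6), Scara5 (74.4), Nhej1 (65.3), Chd9 (64.6), Slc12a3 (63.7) and the glycogen-targeting gene Ppp1r3c (61.7). The 2 Ptpn1 sites lay 77.1 and 99.6 kb outside the gene body. At list members they included Zbtb16 (56.6), Tat (53.5), Bcl6 (49.5), G6pc (44.2), Got1 (43.5), Acly (36.2; 4 of 4 peaks), Serpina1c (35.9; 2 of 2), Cyp7b1 (35.3; 6 of 8), Thrsp (32.0), Dgat2 (29.7; 4 of 6), Cyp7a1 (29.3; 3 of 6), Cebpb (28.0; 7 of 10) and Acadm (22.6; 4 of 4). Of 30011 control peaks, 10523 (35.1%, 34.5 to 35.6) had no dKO peak, and 3874 of 23362 dKO peaks (16.6%, 16.1 to 17.1) had no control peak. The dKO-only peaks were led by Mmp19 (56.5), C1qtnf6 (39.3), Ptpn1 (35.6), Chd9 (34.2), Ctif (33.4), Rnf126 (31.3), Slc28a1 (28.7) and Slc45a1 (27.5). The Mmp19, Chd9, Ctif, Rnf126 and Slc28a1 sites had a control peak within 377 bp, and the control-only Chd9 and Ppp1r3c sites a dKO peak within 462 bp.

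The dKO vehicle list was shorter although its tag total was higher. Before filtering it held more putative peaks than control vehicle, 51920 against 50102. The filter against input then removed 19809 in dKO and 12340 in control, and the local filter 8748 and 7750. At equal length each class held 5979 peaks (25.6%). Of the strongest 20% of control peaks 7.18% were control-only, and of the weakest 20% 69.2%; above the median tag count 2116 (14.1%) were. Among the strongest 20%, 47.3% of control-only against 8.33% of shared control peaks had less than 8-fold over the local 10 kb, so many lay near the local limit of calling. For dKO-only peaks the shares were 0.877% and 48.8%, with 269 peaks (2.30%) above the median, and 2496 (15.7%) with at least 8-fold over input. No gene list passed Fisher's exact test over peaks or permutation of genes in this comparison. By the Cochran-Mantel-Haenszel test within classes of tag count, control-only peaks were more frequent than at other genes for hepatocyte identity (n = 94 peaks, odds ratio 2.77, 1.72 to 4.46, adjusted p = 0.00148), fatty acid oxidation and ketogenesis (n = 50 peaks, 2.52, 1.36 to 4.67, adjusted p = 0.0291) and gluconeogenesis (n = 109 peaks, 2.26, 1.42 to 3.59, adjusted p = 0.0176). Hepatocyte members with control-only peaks were led by Serpina1c, Trf (25.5), Cps1 (24.0) and Hnf4a (22.4), and fatty acid oxidation members included Acadm, Cpt1a (18.9) and Cyp4a10 (18.0). The same lists had unstratified odds ratios of 1.26, 1.64 and 1.03, and the stratified test was added after the data were seen. Neuronal genes, from a tissue not sampled, had 4 control-only peaks among 30 (odds ratio by strength 0.278, 0.0818 to 0.945), which did not pass after adjustment. Endothelial, stellate and cholangiocyte markers had 16 of 36 (44.4%) and Kupffer cell and other leukocyte markers 4 of 10, and neither passed.

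**Figure D3:**
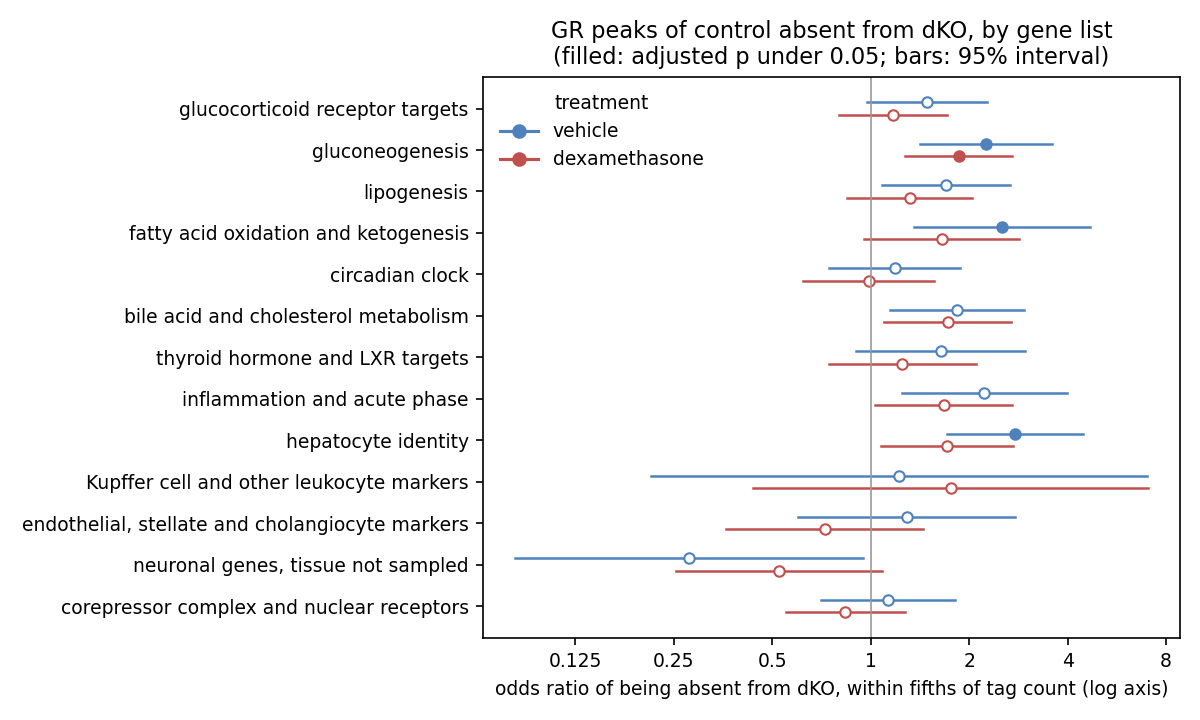
Odds ratio (log axis) for GR peaks of control liver assigned to each of 13 gene lists to be absent from dKO, within classes of tag count; bars are 95% intervals and filled points have an adjusted p under 0.05. Hepatocyte identity stood at 2.77 under vehicle and gluconeogenesis at 1.86 under dexamethasone.

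Under dexamethasone 24720 GR peaks were shared by the genotypes, among them the strongest sites of Fkbp5, Tat, Per1, Pck1, G6pc, Ppargc1a and Tsc22d3. Control liver had 16133 further peaks (39.5%, 39.0 to 40.0), the strongest near Sec22c (102.6), Hmcn2 (94.7), Agtpbp1 (83.3), Dab2 (80.9), Ptprd (74.8), Zbtb16 (74.3) and Lpin1 (71.6). At list members Arrdc2 (54.3; 2 of 3), Orm1 (53.6), Thrsp (50.0), Klf15 (49.5), Saa1 (45.5), Mt1 (43.0), Cebpb (42.5; 5 of 12), Serpina1c (41.6; 2 of 2), Pdk4 (34.3; 4 of 10), Elovl6 (30.3; 10 of 21), Per2 (26.8; 5 of 7) and Clock (25.3; 3 of 3) had such peaks. Of dKO peaks 3658 (12.9%, 12.5 to 13.3) had no control peak, led by Acot2 (43.7), Mical2 (43.7), Gse1 (37.8), the circadian repressor Nfil3 (37.6), the phosphatase gene Dusp1 (36.4), Snx18 (34.5), Synpo (34.3) and Il1rap (33.8). The Gse1, Nfil3 and Il1rap sites had a control peak within 330 bp, and the control-only Sec22c site a dKO peak 239 bp away. At equal length each class held 7545 peaks (26.6%). Control-only peaks were 11.1% of the strongest 20% and 74.7% of the weakest 20%, with 4269 (20.9%) above the median; dKO-only peaks were 3.05% and 32.2%, with 781 (5.50%) above it. Less than 8-fold over the local 10 kb had 52.0% of the strongest control-only and 77.5% of the strongest dKO-only peaks, against 12.6% and 22.6% of shared peaks.

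Glucocorticoid receptor targets had control-only peaks less often than other genes under dexamethasone, at 41 of 164 (25.0%) against 40.0% (odds ratio 0.499, Fisher's exact test, adjusted p = 0.0125). Zbtb16, Arrdc2, Mt1, Cebpb, Fkbp5 (41.0; 2 of 13) and Klf9 (36.5) were the members with the strongest of them. Within classes of tag count the odds ratio turned to 1.17 (Cochran-Mantel-Haenszel test, adjusted p = 0.634), and over genes to 1.52 (Fisher's exact test, adjusted p = 0.775). Gluconeogenesis genes had control-only peaks more often at equal strength (1.86, 1.28 to 2.71, Cochran-Mantel-Haenszel test, adjusted p = 0.0291) and not without strata (odds ratio 0.914, Fisher's exact test, adjusted p = 0.869) or by permutation of genes (difference of -2.14 points, adjusted p = 0.955). Kupffer cell and other leukocyte markers had 5 control-only peaks of 10, and endothelial, stellate and cholangiocyte markers 18 of 50 (36.0%); neither passed.

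**Figure D4:**
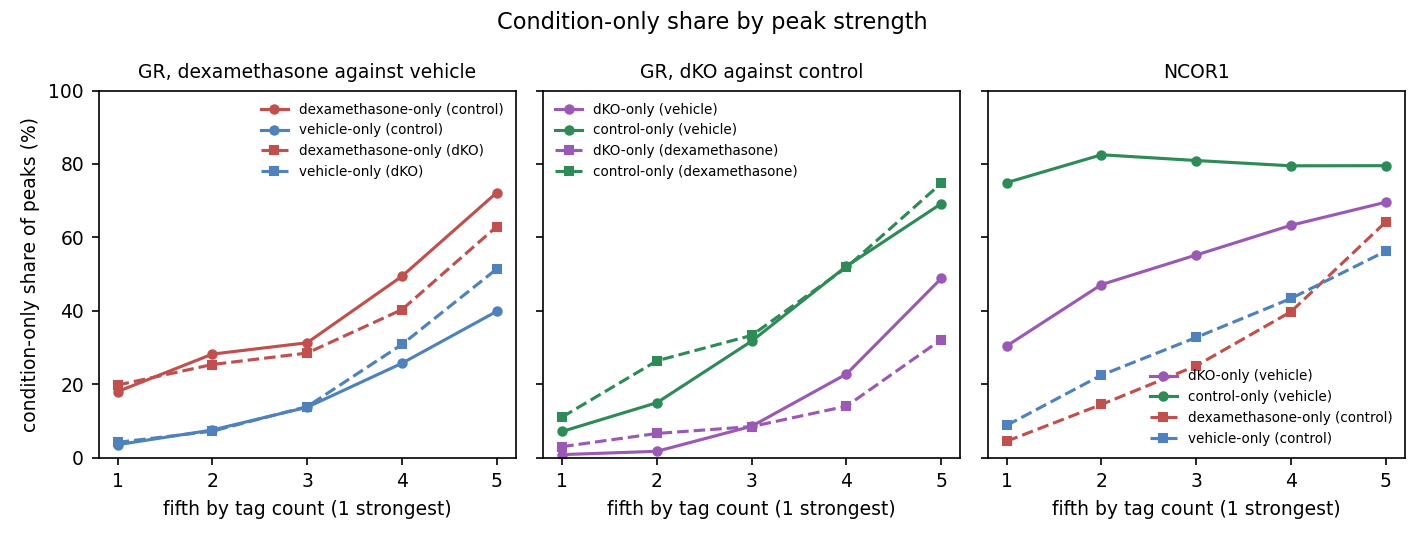
Share of condition-only peaks (%) in each of 5 equal classes of a list by tag count, from strongest (1) to weakest (5), for GR by treatment, GR by genotype and NCOR1. GR shares climb to as much as 74.7% in the weakest class, while NCOR1 control-only peaks stay between 74.9% and 82.5% throughout.

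NCOR1 peaks of control liver were mostly missing in dKO liver, at strong and weak sites alike. Of 39458 control vehicle peaks, 31361 (79.5%, 79.1 to 79.9) had no dKO peak, among them the strongest near Map3k13 (304.4), Mad1l1 (238.3), Cpne5 (203.7), Glt1d1 (168.2), Lrp1 (153.9), Tmem217 (153.9), Stx1a (153.9) and Cnpy3 (149.9). They included all NCOR1 peaks of Pck1 (97.3; 3 of 3), G6pc (95.4; 6 of 6), Tat (7), Per1 (2), Ppargc1a (16), Mt2 (93.7; 3 of 3) and Abcg8 (121; 4 of 4), a sterol transporter. At Ppara 20 of 21 (103.5), at Elovl6 20 of 21 (91.4), at Mlxipl 8 of 9 (111.7), at Cebpb 9 of 13 (147.1), at Rora 37 of 43 and at Cyp7a1 5 of 6 peaks were control-only. The share was 74.9% among the strongest 20% and 79.5% among the weakest 20%, with 15613 (79.1%) above the median. Nr1d1 was an exception: its 3 control peaks were all in the dKO list, the strongest (chromosome 11, 98783363 to 98783563) at 113.9 in control and 74.7 in dKO. The strongest peak of Arntl was likewise called in both, at 100.4 and 93.9. In dKO, Arntl held 7 peaks, Fkbp5 3, G6pc 2, Tsc22d3 1 and Cyp7a1 1, against 7, 12, 6, 12 and 6 in control.

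The dKO list itself held 17282 peaks, of which 9185 (53.1%, 52.4 to 53.9) had no control vehicle peak; 2061 of these were called in control dexamethasone liver. Apart from a site with no gene within 100 kb (62.1), the strongest lay near Dhrs3 (49.2), Rnf144a (44.4), Camk2n1 (40.1), Adam19 (39.2), Psen2 (38.4), Tns1 (36.9) and B4galt1 (36.1); the Camk2n1 and Adam19 sites had a control vehicle peak within 406 bp. All of these sites but Dhrs3 and Rnf144a had an NCOR1 peak in control dexamethasone liver, from 5.01 at the site with no gene to 35.2 near Camk2n1. Kdr, the endothelial VEGF receptor, had 13 dKO-only peaks of 16 (28.1), and the endothelial adhesion gene Pecam1 6 of 8 (24.6). Endothelial markers went both ways in all peaks, dKO against control vehicle. Kdr had 16 against 6, Pecam1 8 against 7, Cdh5 5 against 3 and Clec4g 4 against 1. Stab2 had 6 against 13, Lyve1 1 against 2 and Fcgr2b 1 against 3. Endothelial, stellate and cholangiocyte markers had 32 of 46 peaks in this class (69.6%) against 52.7% of other peaks, which did not pass (odds ratio 2.05, Fisher's exact test, adjusted p = 0.192). Thyroid hormone and LXR targets had fewer, at 8 of 33 (24.2% against 52.8%; odds ratio 0.286, Fisher's exact test, adjusted p = 0.0392). Those were Abcg1 (19.8; 4 of 7), Thrsp (15.7), Srebf1 (13.5), Abca1 (10.9; 1 of 9) and Mylip (9.16). That call was lost within classes of tag count (0.384, Cochran-Mantel-Haenszel test, adjusted p = 0.0973) and over genes (0.619, Fisher's exact test, adjusted p = 0.789). With the 17282 strongest peaks of each list, 13645 (79.0%) were in each class. Above the median tag count 3592 dKO peaks (41.6%) were dKO-only, and 5795 (61.5%) with at least 8-fold over input.

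Hepatocyte identity genes had control-only NCOR1 peaks more often than other genes (131 of 146, 89.7% against 79.0%). The odds ratio was 2.32 (Fisher's exact test, adjusted p = 0.0392), and 2.55 within classes of tag count (1.49 to 4.37, Cochran-Mantel-Haenszel test, adjusted p = 0.0176). Fgb (95.4), Apoa2 (93.1), Hnf4a (90.3; 9 of 10), Fgg (69.5), Cebpa (68.6) and Serpina1a (67.2; 7 of 7) led, and 23 of the 24 members had such a peak. The odds ratio over genes was 3.92 and did not pass (Fisher's exact test, adjusted p = 0.553), nor did 1.72 within 10 kb (Fisher's exact test, adjusted p = 0.441) or permutation of genes (adjusted p = 0.486).

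Most NCOR1 peaks of control liver were called under both treatments. A total of 26532 peaks were shared; 11168 of 37700 dexamethasone peaks (29.6%, 29.2 to 30.1) and 12926 of 39458 vehicle peaks (32.8%, 32.3 to 33.2) were not. Dexamethasone-only peaks were led by Fam71e1 (94.9), Fpgs (79.0), Acsl1 (64.9), Ptpn1 (57), Frmd8 (56.1), Nr1d1 (55.1) and Ephb2 (54.0), and by Gpt2 (51.6), Nfil3 (48.2), Apob (44), Irs2 (41.3) and Insig2 (39.6) among list members. Vehicle-only peaks were led by Fpgs (108.9), Fam71e1 (101.3), Nfic (89.2), Frmd8 (87.8), Poc1a (82.7), Rassf8 (81.6), Slc25a47 (79.6) and Wrnip1 (77.6). Fpgs, Fam71e1 and Frmd8 stand in both classes, with peaks 225 to 413 bp apart. Vehicle-only list members were led by Fbp1 (72.3), a gluconeogenic enzyme, Cebpb (70.3), Mt1 (69.5), Cebpa (66.1), Tef (60.8; 5 of 6), Cyp27a1 (60.5), Tat (53.2; 4 of 7), Hnf4a (50.9) and Mlxipl (48.4). Among the strongest 20% of peaks 4.52% of dexamethasone and 8.84% of vehicle peaks were condition-only, and among the weakest 20% 64.2% and 56.3%. Above the median tag count there were 2276 (12.1%) and 3661 (18.6%), and with at least 8-fold over input 7151 dexamethasone-only peaks (29.6%). The vehicle list came from 1 library and the dexamethasone list from 2. Under dexamethasone NCOR1 held 15 peaks at Ppargc1a, 11 at Arntl, 11 at Tsc22d3, 10 at Fkbp5, 7 at G6pc, 6 at Cyp7a1, 4 at Nr1d1, 3 at Tat, 3 at Pck1 and 1 at Per1.

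Among dexamethasone-only NCOR1 peaks glucocorticoid receptor targets (17.2% against 29.5%, odds ratio 0.497) and hepatocyte identity genes (16.5%, odds ratio 0.473) had lower shares, each with adjusted p = 0.0392 by Fisher's exact test. Members with such peaks included Irs2, Bcl6 (28.9), Fkbp5 (24.1; 4 of 10), Cdkn1a (23.7) and Sgk1 (22.6), and Apob, Ass1 (34.8), Cyp3a11 (25.5) and Cebpa (21.4). Within classes of tag count both calls were lost, with odds ratios of 1.07 and 0.896, and over genes they were 1.15 and 0.727. Vehicle-only peaks were more frequent at lipogenesis genes (2.14, 1.5 to 3.06, adjusted p = 0.0017) and fatty acid oxidation genes (2.18, 1.38 to 3.43, adjusted p = 0.0194) by the Cochran-Mantel-Haenszel test, while Fisher's exact test without strata gave odds ratios of 1.2 and 1.04. By permutation of genes neither was called (adjusted p = 0.909 and 0.980). Lipogenic members were led by Mlxipl, Srebf1 (45.0), Insig2 (43.9; 4 of 7) and Fads2 (39.1), and oxidation members by Ehhadh (44.2; 5 of 6), Ppara (43.0; 7 of 21), Cpt1a (36.0) and Plin2 (33.2).

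NCOR1 lay at 48.9% of control dexamethasone and 54.3% of control vehicle GR peaks, where the mean chance overlap was 0.598% and 0.633%. These shares include NCOR1 peaks also seen in dKO. NCOR1-antibody peaks of the dKO list lay at 13.2% and 14.7% of the same GR peaks, with mean chance overlaps of 0.273% and 0.275%. The shifts take no account of chromatin where many antibodies give signal, so exceeding them does not by itself show co-occupancy. At Fkbp5 the main GR site carried NCOR1 peaks of 29.5 under vehicle and 33.6 under dexamethasone, at Per1 36.3 and 30.3, at Pck1 97.3 and 72.5 and at Cyp7a1 67.0 and 58.1. The strongest GR sites of Tat, G6pc and Tsc22d3 carried none. With peaks also seen in dKO removed, NCOR1 was at 32.7% of dexamethasone-only and 41.7% of shared GR peaks (odds ratio at equal strength 0.874, 0.836 to 0.914). The direction differed between classes of tag count, from 37.0% against 63.0% among the strongest 20% to 37.1% against 27.8% in the middle class. At vehicle-only GR peaks the share was 47.9% against 41.0% (1.17, 1.10 to 1.25). Both depended on the NCOR1 list used. With the other treatment's list they were 0.514 and 0.585, with lists of equal length 0.958 and 0.907, and the vehicle-only value was 1.03 with at least 8-fold over input. At equal tag count, fold over local and fold over input they were 0.646 and 0.828. The next shares use lists of 37700 NCOR1 peaks each, with peaks also seen in dKO kept. There, dexamethasone-only GR sites carried NCOR1 at 41.0% under dexamethasone and 27.5% under vehicle, shared sites at 54.1% and 51.8%, and vehicle-only sites at 46.3% and 60.3%. Seen from NCOR1, 24.8% of its dexamethasone-only peaks lay on dexamethasone-only GR peaks, against 14.8% of its shared peaks (1.77, 1.66 to 1.88). On GR peaks of any class lay fewer of them, 38.2% against 59.2% (0.682, 0.649 to 0.718), and of the vehicle-only NCOR1 peaks 17.1% lay on vehicle GR peaks against 53.1% (0.273, 0.259 to 0.289).

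GR peaks absent from dKO liver carried NCOR1 in control liver more often than those present, at equal strength. Here NCOR1 peaks also seen in dKO were removed, which raised the odds ratios, as given below. Under vehicle NCOR1 was at 59.9% of the 10523 absent and 32.7% of the 19488 present peaks (3.35, 3.17 to 3.55). Under dexamethasone it was at 40.0% of 16133 and 36.9% of 24720 (1.85, 1.76 to 1.94; odds ratio without strata 1.14). The excess under dexamethasone was absent among the strongest 20% of GR peaks, at 56.5% of absent and 58.5% of present peaks. At equal tag count, fold over local and fold over input the values fell to 2.18 and 1.40, and with all NCOR1 peaks besides to 1.60 and 1.16. The removal thus favours the excess. Among the strongest 20% of vehicle GR peaks it took the share with NCOR1 from 50.9% to 38.3% at present peaks. At absent ones it went from 78.7% to 72.2%. Among the weakest 20%, at equal tag count and folds, the odds ratio went from 1.05 to 1.62. The other alternatives ranged from 2.5 to 6.69 and from 1.66 to 2.10. The reverse arrangement was also seen: GR peaks found in dKO and not in control under vehicle carried dKO-only NCOR1-antibody peaks at 11.6% (451 of 3874), against 2.67% of shared peaks (2.97, 2.54 to 3.48). Sites with control NCOR1 cannot hold such peaks by definition. With all dKO NCOR1-antibody peaks, at equal tag count and folds, the value was 1.31 (1.19 to 1.44). It rested on classes 4 and 5 of tag count, the weakest (1.42 and 1.34), while in classes 1 to 3 each interval held 1.

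**Figure D5:**
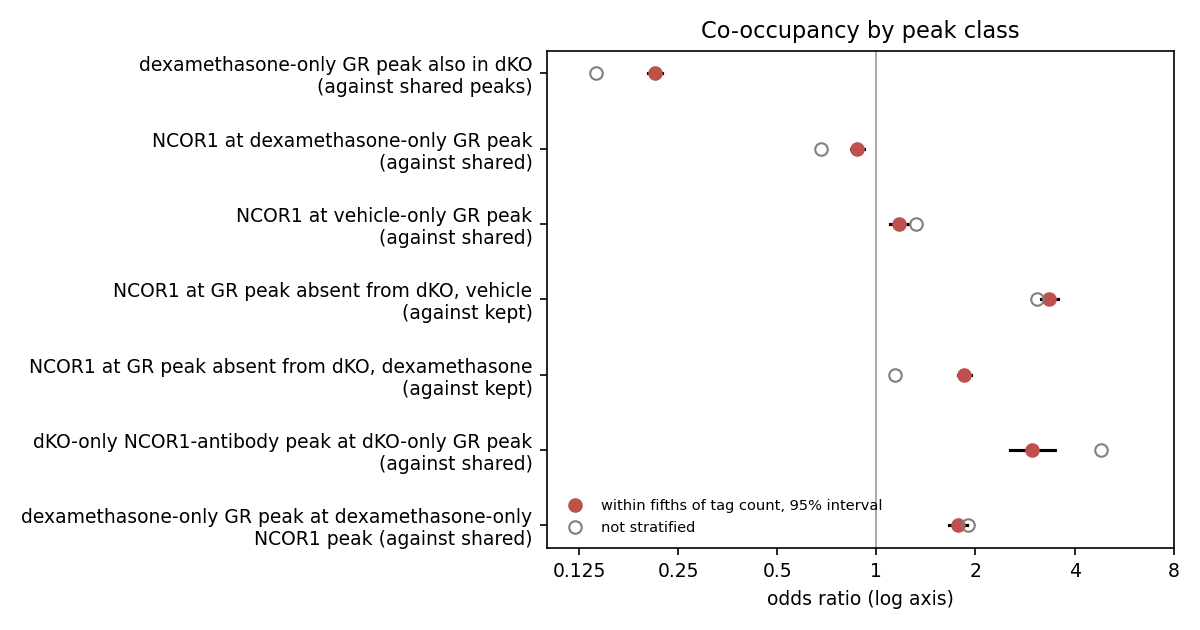
Odds ratios (log axis) that a class of peaks is also bound in another list, within classes of tag count (filled, 95% intervals) and not stratified (open). NCOR1 at GR peaks absent from dKO stood at 3.35 under vehicle and 1.85 under dexamethasone, and dKO-only NCOR1-antibody peaks at dKO-only GR peaks at 2.97. For NCOR1 at GR peaks, NCOR1 peaks also seen in dKO were left out.

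Of the 156 tests of gene lists, 6 passed after adjustment over peaks and 8 within classes of tag count. With genes instead of peaks as the unit none passed, either by Fisher's exact test (lowest adjusted p = 0.279) or by permutation of genes (lowest adjusted p = 0.454). Unadjusted p fell under 0.05 in 21 of the tests over genes by Fisher's exact test and in 16 by permutation. With lists of equal length 23 passed, with peaks within 10 kb of a gene 1, and with centres within 500 bp 10.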

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

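All tests in this part were chosen only after the results they bear on were known. That of chromatin replaces an earlier test whose outcome was partly fixed by its definition.

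The link between NCOR1 and GR peaks missing in dKO liver differed between treatments. Its odds ratio was 3.35 under vehicle and 1.85 under dexamethasone, a ratio of 1.81 (1.70 to 1.94, from 1000 bootstrap draws over 532 blocks of 5 Mb). Both values leave out NCOR1 peaks of the dKO list, which was profiled under vehicle alone. With all NCOR1 peaks, at equal tag count, fold over local and fold over input, they were 1.60 and 1.16, and the ratio of these was not tested. The interval does not cover this choice. The treatments differ in their NCOR1 lists too, from 1 and 2 libraries.

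The dKO liver had fewer GR peaks than control liver under both treatments. Under vehicle this held only after filtering, since the dKO list began with 51920 putative peaks against 50102 in control. Under dexamethasone the putative peaks were fewer too, 60479 against 72489. Fragment lengths in the headers were 164 and 160 bp in the dKO vehicle and dexamethasone lists, and 140 and 142 bp in control. Whether they bear on the filters was not tested. Lower depth is argued against, since the dKO lists held at least 1.06 times as many tags as the control lists. Evenly weaker enrichment as the whole cause stays open. Among the strongest 80% of vehicle peaks, a part set after the values were seen, the missing ones carried NCOR1 more often. At equal tag count, fold over local and fold over input the odds ratio was 1.97 (1.81 to 2.14, with all NCOR1 peaks). Without strata it was 4.68, and matching by 5 classes of each measure may leave differences of strength within a class. For the weakest 20%, with 4153 of the 10523 missing peaks, the value was 1.05 (0.938 to 1.19). Under dexamethasone it was 1.16 (1.10 to 1.22). Classes of tag count there went both ways, from 0.620 among the strongest 20% to 1.67 in the middle class. Chromatin that is open in 1 genotype and gives both antibodies signal may account for the link with NCOR1, because dKO-only GR peaks carried NCOR1-antibody peaks of the dKO list more often than shared ones, at equal tag count and folds (odds ratio 1.31, 1.19 to 1.44). That excess lay in classes 4 and 5 of tag count, the weakest (1.42 and 1.34). In classes 1 to 3 the values were 0.472, 1.43 and 1.05 and each interval held 1, so at stronger sites the test does not decide. A loss of GR binding that follows from the loss of NCOR1 at the same sites stays open, and these lists do not separate it from a change of chromatin. The knockout may include more than NCOR1. Loss of another gene in the same livers cannot be told apart from loss of NCOR1 here.

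A second observation came from a measure outside the comparisons, the ratio of a peak's tags to its findPeaks score. It reached 2 or more at 30 GR peaks in dKO vehicle, 27 in control vehicle, 14 in control dexamethasone and 11 in dKO dexamethasone, with sites near Lrriq1 (tag count 243.7 in dKO vehicle), Pou4f3 (233.4), Plcg2 (212.2) and Cdh23 (205.8). Amplification of single fragments in 1 library is argued against: all 30 loci were called in all 4 GR lists, and in 246 of 246 pairs (100%) the ratio at the same locus in another list exceeded that of peaks of equal strength. The NCOR1 lists held 0 such peaks. The GR antibodies, the library preparation without size selection and the high sonication named in the headers cannot be told apart as a source, because they differ together. All 30 loci had higher tag counts under vehicle than under dexamethasone in both genotypes (medians 170.55 and 110.55 in control, 158.3 and 92.2 in dKO), which was not explained. The 30 loci were picked in the dKO vehicle list, so the dKO comparison is drawn from the list that picked them. Loci picked in a dexamethasone list were not compared in this way. No biological explanation was tested. Removing peaks with stacked tags left the overlap results within 1.5 times their values, which was bound to hold with at most 30 peaks removed from a list.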

How the results depend on the processing

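The settings with centres within 500 bp, 20 classes of tag count, equal tag count and folds over local and input, gene lists by strength, the nearest gene end, permutation of genes and without stacked tags were chosen after seeing the data. No paired analysis was possible because each deposited list pools its replicates; for the same reason leaving out each replicate and the replicate block were not run, and the motif alternatives were not run without a genome. Over all results 202 of 274 alternatives kept the direction, the side of the threshold or the size. Of the 58 for the 5 stratified odds ratios 53 did: dexamethasone-only peaks in dKO 0.175 to 0.310, NCOR1 at absent GR peaks 2.18 to 6.69 (vehicle) and 1.40 to 2.10 (dexamethasone), and 1.60 and 1.16 with equal folds and all NCOR1 peaks together.

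Peaks above the median tag count, by construction fewer, gave 4917 dexamethasone-only and 1026 vehicle-only GR peaks in control, 3329 and 804 in dKO, 269 dKO-only and 2116 control-only under vehicle, and 781 and 4269 under dexamethasone. For NCOR1 they gave 3592 dKO-only, 15613 control-only, 2276 dexamethasone-only and 3661 vehicle-only. At equal list length both classes held 8864 (control, by treatment), 5979 (vehicle, by genotype) and 7545 (dexamethasone, by genotype), and NCOR1 control-only 13645; equal lengths force equal classes. At least 8-fold over input left 2496 dKO-only GR peaks under vehicle, 5795 dKO-only and 7151 dexamethasone-only NCOR1 peaks. Other overlap rules and autosomes alone moved no class by more than 1.5 times.

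NCOR1 at dexamethasone-only GR peaks went to 0.958 at equal length. At vehicle-only peaks it went to 1.03 with 8-fold over input, and turned to 0.907 at equal length, 0.585 with the other NCOR1 list and 0.828 at equal tag count and folds; the cause was not tested. The 6 gene list calls became 1 within 10 kb, 0 over genes, 23 at equal length, 10 with centres within 500 bp and 0 by permutation of genes. Odds ratios turned over genes for hepatocyte identity, dexamethasone-only GR in control (1.55), and for glucocorticoid receptor targets, control-only GR under dexamethasone (1.52; by strength 1.17) and dexamethasone-only NCOR1 (1.15; by strength 1.07). The cause was not tested. For 13 results of single gene lists 104 alternatives were run. Of these 71 stayed called or uncalled as before, 20 lost a call, 8 gained one and 5 turned. Only the 6 results called by Fisher's exact test had a call to lose. The others were called only within classes of tag count. For those, staying uncalled counted among the 71, and the stratified test that picked them counted among the gains. Within 5000 bp of a gene end lay 25.7% (dKO dexamethasone), 29% (dKO vehicle), 26.4% (control dexamethasone) and 29.4% (control vehicle) of GR peaks, and 39.6% (dKO vehicle), 31.9% (control dexamethasone) and 34.4% (control vehicle) of NCOR1 peaks. Depth limits the weak peaks, where condition-only shares were highest in each class except control-only NCOR1 peaks.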

Other observations

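Of the tests in this part, that on leukocyte markers was set before its result was seen; the others were chosen only after the results were known.

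In the dKO list 37.1% of all genes had an NCOR1-antibody peak. Of the corepressor complex and nuclear receptors list 15 of 16 genes had one (odds ratio 25.5 against all other genes, Fisher's exact test, adjusted p = 3.3e-05). Of the 19 clock genes 17 did (odds ratio 14.4, Fisher's exact test, adjusted p = 3.3e-05), with Npas2 (tag count 124.8) and Arntl (93.9) among its strongest. Of the 13 lists 8 passed with a higher share than all other genes, among them glucocorticoid receptor targets (79.2%, adjusted p = 0.000182 by Fisher's exact test) and lipogenesis and fatty acid oxidation (66.7% each, 0.00965). In control vehicle liver all 19 clock genes did. Of the 24 hepatocyte identity genes, all had an NCOR1 peak in control vehicle and 13 in dKO. Of the 24 glucocorticoid receptor targets 22 had one in control vehicle and 19 in dKO. Neuronal genes had few: 1 of 18 in dKO (Fisher's exact test, adjusted p = 0.00832) and 6 of 18 in control vehicle, where 52.2% of all genes had a peak and the difference did not pass (adjusted p = 0.177). For GR, however, 13 of 18 neuronal genes had a peak in every list. Fisher's exact test called that share higher than at other genes in dKO vehicle (odds ratio 3.24, adjusted p = 0.0387) and dKO dexamethasone (2.96, adjusted p = 0.0441), and in neither control list. This test takes no account of gene length, and it can call genes of a tissue not sampled. The difference between gene groups was not tested.

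The genes with the most condition-only peaks were mostly long ones, named here after their values were seen. In control liver Zbtb20 had 24 dexamethasone-only GR peaks of 41, Foxp1 21 of 33, Magi1 20 of 25 and Lpp 19 of 45. Prkce held 12 vehicle-only peaks of 32. Between genotypes Arid1b (20 of 39), Zbtb20 (17 of 41), Foxp1 (16 of 33), Lpp (16 of 45), Magi1 (16 of 25) and Sox5 (16 of 37) had the most control-only peaks under dexamethasone. Among dKO-only NCOR1-antibody peaks Rad51b (16 of 23), Etv6 (14 of 16), Kdr (13 of 16) and Nav1 (13 of 15) led. Peaks were not scaled for gene length, which was 758.7 kb for Zbtb20 and 46.2 kb for Kdr.

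Whether the response of any gene group differed between genotypes or between treatments was tested by permutation of genes in 26 tests of 10000 permutations each. None passed. The lowest adjusted p was 0.286 (permutation p 0.011 before adjustment), for the dexamethasone-only GR share of bile acid and cholesterol genes (26.0% in control, 44% in dKO).

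NCOR1-antibody peaks remain in dKO liver, and 41.2% of them were called in neither control list. NCOR1 left evenly at all sites by incomplete deletion is argued against as the whole source: 20.5% (19.6 to 21.4) of the weakest 20% of control vehicle peaks were found in dKO, against at most 0.370% by chance, although 74.9% of the strongest 20% were missing. Endothelial cells that keep NCOR1 stay open: their marker peaks against all other peaks numbered 41 in dKO and 35 in control (odds ratio 2.65, 1.64 to 4.28; permutation of genes, p = 0.049), but without Kdr the odds ratio was 1.95 and the permutation p 0.201, and against hepatocyte identity genes, 89.7% of whose control peaks were control-only, it was 8.05. Too few peaks decide on stellate cells (3.39, 0.388 to 40.5), cholangiocytes (0.282, 0.0315 to 1.2), leukocytes (3.06, 0.633 to 12.3, against hepatocyte genes; 1.00 against all other peaks) or all of these alike: endothelial against cholangiocyte peaks gave 9.18 (1.95 to 87.8), with a lower limit of 0.989 without Sox9. No file shows which cells carry the deletion, and open chromatin that the antibody meets in dKO hepatocytes stays open.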
